A study of Homo sapiens with 4 samples.

How the data were processed

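Total RNA from 4 samples of the human hepatocellular carcinoma line Hep3B was profiled on 1-colour Agilent expression arrays: 2 mock clones and 2 clones in which a transcript called fusion HBx had been stably knocked down by RNA interference. Per the labels' protocols, 100 ng of total RNA was converted to Cy3-labelled cRNA with Agilent's low-input labelling kit for each array. Groups and clone numbers were taken from the sample titles. The labels call the samples clones and do not say how many cultures or extractions each stands for. The limma p-values therefore measure the spread between these clones only. The p-values of camera at a preset correlation and of permutations across genes compare genes with other genes, and do not measure the spread between clones.

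The deposited scanner files hold 1 array each. Per the file headers, they were made with Agilent Feature Extraction 10.10.1.1, a name that the submitters' processing notes also give without a version. Per the file headers, the processed signal intensity of each spot is background-subtracted and detrended on a linear scale, and it is not normalized between arrays. The deposited median signal and local background intensities are raw pixel medians. The deposited table of the whole series holds log2 values, with column medians of 5.93 and 5.93 in the mock clones and 5.94 and 5.94 in the knockdown clones. Its direction follows the scanner signal: across probes, its values correlated with the log2 processed signal of the same array at r of 0.982 to 0.986, and at 0.995 to 0.997 for probes well above background (genes are not independent replicates). The 4 columns have nearly the same median, while the authors' background step and normalization are not given in the sources used here. That table was used only as an alternative.

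All 4 arrays were on 1 slide and in 1 scan, per the file headers. Both mock arrays lay in the first row of the slide and both knockdown arrays in the second, so slide row and group cannot be told apart, and no fit with the slide as a block was run. Each array held 62976 features, of which 58717 were not controls. Between 58.8% and 64.9% of these spots were well above background, 0 were saturated, and the median coefficient of variation of repeated probes was 4.37% to 4.77%. The number of arrays, 2 per group, limits the precision of every value.

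The main values were the log2 processed signals minus the 75th percentile of the non-control spots of each array. Control spots and spots with an outlier flag were left out, and spots of the same probe were averaged. This left 50584 of 50599 probes, 15 having no unflagged spot on some array. The scanner files carry no column of gene names, so each probe's accession was matched without its version to the RefSeq gene table of assembly GRCh38.p14. A gene symbol was found for 28174 probes, covering 20503 symbols, and the other 22425 probes kept the accession in the file. The headers name the older hg19/GRCh37 assembly for the array design, so no coordinates are given. For a gene with several probes, the probe with the highest mean over the 4 arrays stood for it, which gave 41164 genes or unnamed transcripts. A gene was tested where this probe was well above background on both arrays of at least 1 group. That left 24225, of which 15605 had a symbol.

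Knockdown was compared with mock in R 4.3.3 with limma 3.58.1, using lmFit and eBayes with an intensity trend, two-sided, and Benjamini-Hochberg adjustment with a threshold of 0.05. The fit had 2 residual degrees of freedom per gene, to which the prior added 3.09. An exact permutation test of a single gene with 2 arrays against 2 cannot give a p below 0.333, so the inference rests on the spread shared across genes. Differences are log2 knockdown minus mock, with the standard error (SE) of the fit, and group values are mean ± SD of the 2 clones. Where a gene was not well above background on either array of a group, its fold is a lower bound. The bright group's mean was set against, for each dim array, the higher of the gene's own signal and the lowest signal of any probe well above background there. Where the gene's own signal was the higher on both arrays, the fitted difference is given and is not called a bound.

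Before the data were examined, 48 gene lists of pathways, complexes and cell type markers were fixed, with a minimum of 5 measured members. They were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. The same lists were run with camera using an estimated correlation and with fry. Older symbols in the lists were updated through the table's synonyms where a single current gene carried them. The listed synthetase names GARS and SARS each belong to more than 1 current gene and dropped out of the PERK and ATF4 list for that reason. Named genes followed a rule fixed at the same time. For the comparison, these were the 12 largest positive and 12 largest negative log2 differences among genes with a symbol past the threshold whose groups did not overlap. For each described list, they were 2 to 4 members, those past the threshold with the largest difference first and then those with the smallest p.

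Alternatives fixed at the same time were another background correction, other normalizations, other filters on dim probes, the mean of all probes, other variance models, the deposited value table, each array left out in turn, and the clone number as a block. The planned background correction (normexp, offset 50) named the mean signal, and the median signal was used in its place because the files give the latter. Scaling on the E1A spike-in probes, a floor on weak signals and a restriction to genes with a symbol were added after seeing the data. The model was tested on simulated data with the spreads of these 24225 genes shuffled across genes, 2 arrays per group, 200 changed genes and 20 runs. It recovered 0.2% of genes changed by 1 log2 unit, 41.6% at 2, 75.9% at 4 and 87% at 6, and 2.3% of its calls were false. Shuffling removed any link between signal and spread, which the intensity trend models. These rates therefore hold for the simulated data and cannot show the recovery or the false calls in the real data. A list shifted by 1 log2 unit was called in 20 of 20 runs, and 0 of 780 tests of other lists were calls. The simulated genes varied independently of each other and the lists were drawn at random. The simulation therefore cannot show how often camera at the preset correlation makes false calls where the genes of a list vary together between clones.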

Results

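The expression of messenger and noncoding RNAs was measured in Hep3B cells, a human hepatocellular carcinoma line that carries integrated hepatitis B virus DNA. HBx is the X protein of that virus, and the labels describe the targeted transcript as a fusion form of it without saying what it is joined to. The question was which genes differ in expression between mock clones and clones with the fusion HBx stably knocked down by RNA interference. There were 2 clones in each group and 1 array per clone. The share of spots well above background was 61.3% and 58.8% on the mock arrays and 64.9% and 63.6% on the knockdown arrays. The 75th percentile of the processed signal, the scaling reference, was 550.4 and 567.7 on the mock arrays and 632.1 and 584.7 on the knockdown arrays. No probe named for HBx or for hepatitis B virus was found by accession among the probes used here, so the level of the targeted transcript was not measured and the labels were not checked against it.

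Of the 48 gene lists tested, the PERK and ATF4 stress response list had the mean farthest from 0 between the groups. Of 24225 genes and unnamed transcripts tested, 172 were higher and 41 were lower in the knockdown clones at the adjusted threshold, and each of these differed by at least 2-fold. A gene symbol was available for 136 of the higher and 35 of the lower ones. At an unadjusted p under 0.05, 2211 were higher and 2410 lower. Among the 213 calls, 24 of the higher genes were not well above background in either mock clone, and 5 of the lower ones were not in either knockdown clone. Across all tested genes, r between the clones was 0.988 within mock, 0.984 within knockdown, and 0.968 to 0.976 between the groups (genes are not independent replicates). The counts depended on single arrays. They were 30 higher and 2 lower without mock clone 1, 25 and 3 without mock clone 2, 82 and 21 without knockdown clone 1, and 405 and 316 without knockdown clone 2, and 20 of the 213 genes passed in each of these 4 fits. With no filter on dim probes 66 were higher and 4 lower, with genes above background on all 4 arrays 117 and 16, with the mean of all probes 138 and 27, and without the intensity trend 84 and 12. Of the settings added after seeing the data, spike-in scaling gave 318 and 46. A floor on weak signals gave 0 and 0 in limma, with 4510 at an unadjusted p under 0.05, and 87 and 7 once the genes at the floor on all 4 arrays were left out.

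**Figure D1:**
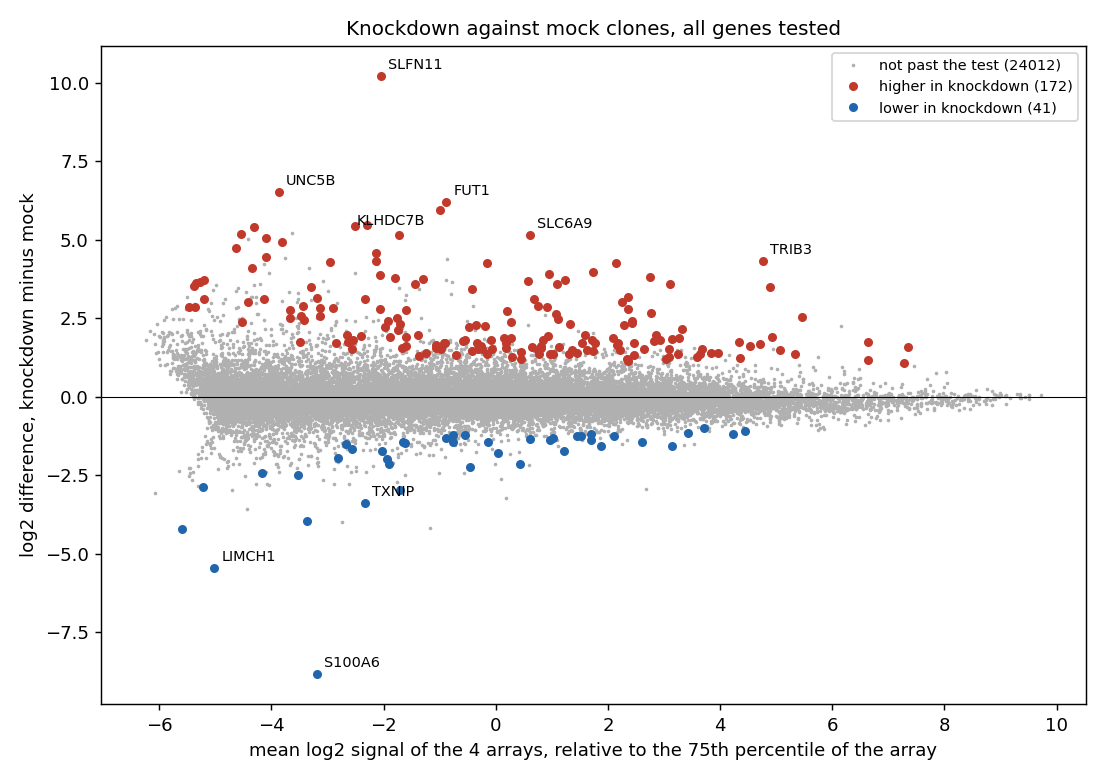
Each point is a gene or transcript tested, with its mean log2 signal over the 4 arrays relative to the 75th percentile of each array on the x axis and its log2 difference, knockdown minus mock, on the y axis. The 172 genes higher in knockdown are red and the 41 lower are blue; the points of genes not well above background in 1 group, SLFN11 and S100A6 among them, are drawn at the recorded signals, so their distance from 0 is not a measured size.

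The largest increase was in SLFN11, a Schlafen family gene whose product acts at stressed replication forks. Its probe (RefSeq NM_001104587) was not well above background in either mock clone, at a log2 signal of -7.15 ± 0.09 (SD, n = 2), and it reached 3.06 ± 0.40 in the knockdown clones. This was at least 254-fold higher on the processed signal (limma adjusted p = 0.00273). UNC5B, a netrin receptor, was at least 19.8-fold higher (limma adjusted p = 0.00857) and VLDLR-AS1, an antisense RNA of the VLDL receptor locus, at least 35.0-fold higher (limma adjusted p = 0.00731). EBF3, a transcription factor, PLAC1, a placental gene, PRPH2, a photoreceptor tetraspanin, MAP1B, a microtubule-associated protein gene, and IRAK3, a negative regulator of Toll-like receptor signalling, were also not well above background in the mock clones. Their bounds were at least 7.84-fold, 10.2-fold, 11.9-fold, 10.01-fold and 6.33-fold higher, with limma adjusted p of 0.0227 to 0.0303. A second MAP1B probe gave a difference of 2.64 log2 units against 5.42, and the 4 probes of VLDLR-AS1 gave 4.17 to 5.45. These bounds are specific to the processed signal. With normexp background correction of the median signals, which adds an offset of 50 to every signal, the log2 differences were 6.42 for SLFN11, 2.78 for UNC5B, 3.12 for VLDLR-AS1, 1.80 for EBF3 and 1.79 for PRPH2, all past the test. MAP1B at 1.76, PLAC1 at 1.62 and IRAK3 at 1.18 were not past it in that setting (limma adjusted p = 0.0576, 0.0644 and 0.0523).

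FUT1, a fucosyltransferase that makes the H antigen, was measured in all 4 clones and was higher by 6.19 log2 units (SE 0.41, limma adjusted p = 0.0236), a 73.0-fold difference. KLHDC7B, a kelch domain gene, was 61.4-fold higher (log2 difference 5.94, SE 0.31), and its 2 probes gave 5.94 and 7.52. SLC6A9, a glycine transporter, rose from -1.96 ± 0.77 to 3.17 ± 0.15 (SD, n = 2 each), a 35.2-fold difference, and its other probe gave a log2 difference of 3.86 against 5.14. ULBP1, a ligand of the NKG2D receptor of natural killer cells, was well above background in 1 of 2 mock clones and was 35.7-fold higher (log2 difference 5.16, SE 0.51), with 3.59 from its other probe. With normexp correction the differences were 4.61 for FUT1, 4.42 for KLHDC7B, 4.48 for SLC6A9 and 3.50 for ULBP1, all past the test. SLFN11, UNC5B, FUT1, KLHDC7B, VLDLR-AS1, EBF3 and SLC6A9 passed the test whichever array was left out, and the other 5 of these 12 genes did not.

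The largest decrease was in S100A6, a calcium-binding protein gene. Its signal (RefSeq NM_014624) was 1.23 ± 1.42 (SD, n = 2) in the mock clones and not well above background in the knockdown clones, at least 112-fold lower (limma adjusted p = 0.0239). LIMCH1, which codes for an activator of nonmuscle myosin, was at least 9.81-fold lower, SPART, the spartin gene, at least 4.25-fold lower, with limma adjusted p of 0.0333 and 0.0291. TENT4B, a noncanonical poly(A) polymerase gene, had a fitted log2 difference of -2.43 (SE 0.29, limma adjusted p = 0.0477), with neither knockdown clone well above background. With normexp correction, S100A6 at -4.36, LIMCH1 at -1.58 and SPART at -0.87 were not past the test (limma adjusted p = 0.0542, 0.0751 and 0.0559), and TENT4B was at -0.85 and past it. COLEC11, a collectin of the lectin complement pathway, was lower by 15.5-fold (log2 difference -3.96, SE 0.33), with 1 of 2 knockdown clones well above background. TXNIP, the thioredoxin-interacting protein gene, was lower by 10.46-fold (log2 difference -3.39, SE 0.34). With normexp correction COLEC11 was at -1.87 and TXNIP at -2.04, both past the test.

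The remaining 6 of the 12 were well above background in all 4 clones. A4GNT, a glycosyltransferase of gastric mucins, differed by -2.97 log2 units (SE 0.29), and CGA, the common alpha subunit of glycoprotein hormones, by -2.48 (SE 0.25). TMEM19, a transmembrane protein gene, differed by -2.24 (SE 0.25), TWF1, twinfilin, by -2.13 (SE 0.14), CD82, a tetraspanin, by -1.99 (SE 0.16), and SLITRK4, a neuronal transmembrane protein gene, by -1.96 (SE 0.24). Their limma adjusted p lay between 0.0236 and 0.0482. With normexp correction these 6 differences lay between -2.12 for A4GNT and -1.03 for CGA, all past the test. Of the 12 lower genes, S100A6 passed whichever array was left out but not with normexp correction, and the other 11 lost the call in at least 1 of the 4 fits. Of the 24 named genes in both directions, 18 passed with normexp correction, 18 without the intensity trend, 10 with no filter on dim probes, and 0 with the floor on weak signals or 13 once the genes at the floor on all 4 arrays were left out.

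The PERK and ATF4 stress response list, which holds genes switched on when translation initiation factor eIF2 is phosphorylated, rose in the knockdown clones. All 34 measured members had a positive difference, with a mean of 2.36 ± 0.93 log2 units (SD over members), and 26 passed the test over all genes while 34 passed adjusted over the list alone. TRIB3, a pseudokinase, rose by 4.31 log2 units (SE 0.22, 19.9-fold) and CHAC1, a glutathione-degrading enzyme, by 4.27 (SE 0.29, 19.3-fold). ATF3, a transcription factor of the ATF family, rose by 3.80 (SE 0.35, 13.9-fold) and STC2, a secreted glycoprotein gene, by 3.78 (SE 0.18, 13.8-fold), with limma adjusted p of 0.0197 to 0.0303 for the 4 genes. The 4 ATF3 probes disagreed, with differences from -0.05 to 3.95. The list mean was 2.52 above the mock mean in knockdown clone 1 and 2.19 in clone 2. Its adjusted p was 2.71e-39 by camera and 0.653 with an estimated correlation.

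The ATF6 and XBP1 list of endoplasmic reticulum chaperones, folding enzymes and degradation factors also rose. Its 31 members averaged 0.94 ± 0.63 (SD over members), with 28 positive, 11 past the test over all genes and 24 higher and 1 lower adjusted over the list alone. MANF, a secreted stress-induced factor, rose by 1.89 log2 units (SE 0.12, 3.71-fold), and DNAJC3, an inhibitor of eIF2 kinases, by 1.80 (SE 0.16, 3.48-fold). HYOU1, an endoplasmic reticulum chaperone, rose by 1.76 (SE 0.19, 3.40-fold) and DNAJB9, a cochaperone of that compartment, by 1.72 (SE 0.15, 3.28-fold), with limma adjusted p of 0.0236 to 0.0412. The adjusted p of the list was 4.21e-19 by camera and 0.653 with an estimated correlation.

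**Figure D2:**
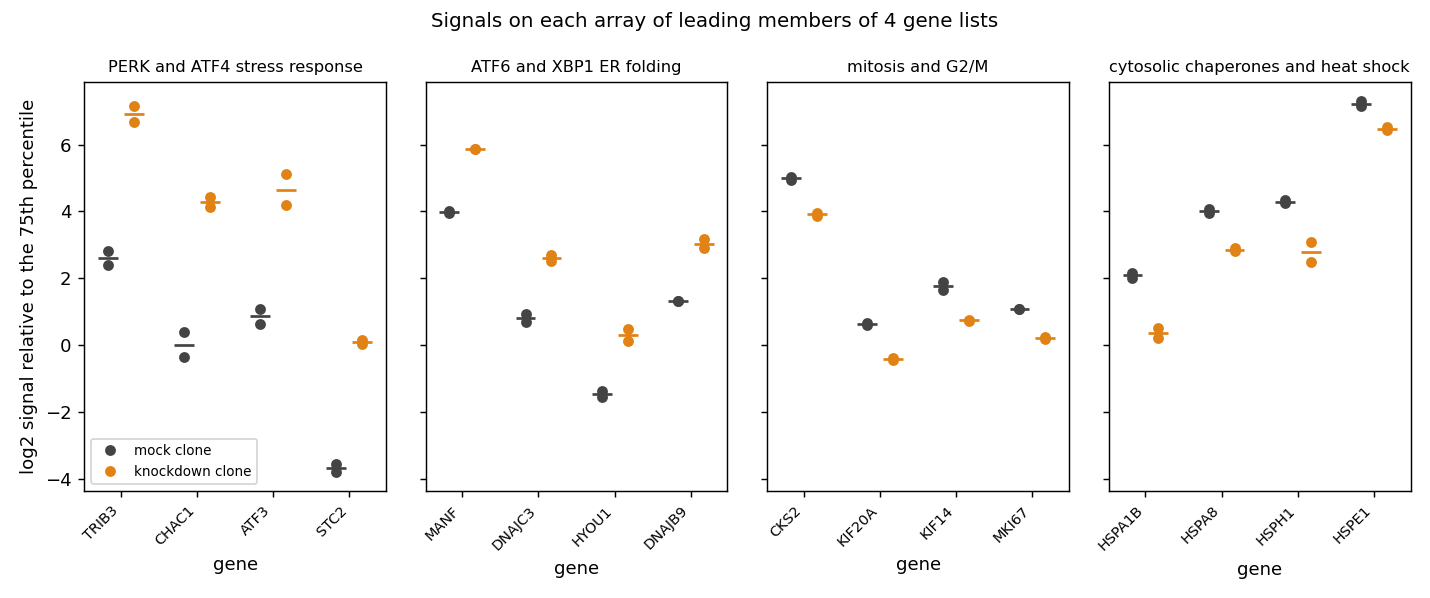
Points are the log2 signals of single arrays relative to the 75th percentile of each array, and horizontal bars are the means of the 2 mock (grey) and 2 knockdown (orange) clones, for the 4 leading members of 4 gene lists. The knockdown clones lie above the mock clones for the 8 genes of the PERK, ATF4, ATF6 and XBP1 lists and below them for the 8 genes of the mitosis and chaperone lists, of which CKS2, HSPA1B and HSPA8 passed the test.

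Genes of cell division fell as groups, by smaller amounts. All 41 measured members of the mitosis and G2/M list had a negative difference, with a mean of -0.67 ± 0.23 log2 units (SD over members). CKS2, a cofactor of cyclin-dependent kinases, passed the test over all genes at -1.08 (SE 0.12, limma adjusted p = 0.0442), and 27 members passed adjusted over the list alone. The kinesin gene KIF20A was at -1.04 (SE 0.14) and KIF14 at -1.03 (SE 0.16), with limma adjusted p of 0.0599 and 0.0705. The list mean lay 0.47 to 0.87 below mock over the 4 pairs of clones; its adjusted p was 1.47e-15 by camera and 0.653 with an estimated correlation.

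The DNA replication and G1/S list fell by less, with a mean of -0.31 ± 0.38 over 41 members, 34 of them negative. Over the other settings its mean lay between -0.37 and -0.16. E2F2, a transcription factor of S phase entry, fell by 1.38 log2 units (SE 0.15, limma adjusted p = 0.0401), the 1 member past the test over all genes, against 3 adjusted over the list alone. PCNA, the replication clamp, was at -0.92 (SE 0.13, limma adjusted p = 0.0623). The adjusted p of the list was 9.39e-05 by camera and 0.792 with an estimated correlation. Histone genes averaged -0.49 ± 0.28 over 25 members, 24 of them negative. In limma, 0 of them passed over all genes and 16 passed adjusted over the list alone, and the smallest p belonged to H4C5 at -0.92 (SE 0.15) and H2BC21 at -1.09 (SE 0.18), with limma adjusted p of 0.0756 and 0.0772. Probes of histone genes can share signal between near-identical copies. The histone list had an adjusted p of 4.15e-08 by camera and 0.653 with an estimated correlation.

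Cytosolic chaperone and heat shock genes fell as a list, opposite to the endoplasmic reticulum chaperones, although the difference between the 2 lists was not itself tested. The heat shock list also holds the mitochondrial chaperonin genes HSPD1 and HSPE1, so it is not purely cytosolic. The 26 members averaged -0.56 ± 0.52 (SD over members) and 23 were negative, with 2 past the test over all genes and 10 adjusted over the list alone. HSPA1B, an inducible HSP70 gene, fell by 1.74 log2 units (SE 0.17, limma adjusted p = 0.0338), and HSPA8, the constitutive HSP70 gene, by 1.15 (SE 0.13, limma adjusted p = 0.0435). HSPA1B is nearly identical to HSPA1A, so the signal of its probe is not assigned to either copy alone. HSPH1 was at -1.51 (SE 0.22, limma adjusted p = 0.0657). The adjusted p of the list was 2.51e-06 by camera and 0.653 with an estimated correlation.

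The metallothionein list, of metal-binding proteins induced by zinc and stress, rose by a mean of 0.84 ± 0.80 over 9 measured members. MT2A rose by 1.97 log2 units (SE 0.24) and MT1E by 1.80 (SE 0.22), each with limma adjusted p = 0.0477, and 6 members passed adjusted over the list alone. Metallothionein genes are near-identical copies, and the 2 MT1E probes gave opposite differences of -1.28 and 1.80. The list's adjusted p was 9.39e-05 by camera and 0.653 with an estimated correlation.

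Targets of Wnt and beta-catenin signalling fell as a list, with a mean of -0.57 ± 1.32 and a median of -0.92 over 22 measured members, 18 of them negative. TBX3, a T-box transcription factor, fell by 1.68 log2 units (SE 0.18, limma adjusted p = 0.0379), the 1 member past the test over all genes. Adjusted over the list alone, 12 were lower and 2 higher. The Wnt feedback gene NKD1 was at -1.89 (SE 0.25) and the transcription factor gene SP5 at -1.03 (SE 0.14), with limma adjusted p of 0.0575 and 0.0591. The list's adjusted p was 0.000119 by camera and 0.653 with an estimated correlation.

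A further 5 lists passed camera with all 4 arrays and did not pass under every setting. Antigen presentation genes averaged 0.33 ± 0.68 over 22 members, with ERAP1, a peptide-trimming aminopeptidase, at 1.03 (SE 0.16, limma adjusted p = 0.0735) and HLA-DMB at 2.87 (SE 0.54, limma adjusted p = 0.0891). The list's adjusted p was 0.0186 by camera, 0.112 without mock clone 2, 0.159 with the mean of all probes (list mean 0.19), and 0.653 with an estimated correlation. Interferon-stimulated genes averaged 0.32 ± 0.59 over 34 members, and UBE2L6, the conjugating enzyme for ISG15, rose by 1.97 (SE 0.24, limma adjusted p = 0.0477) while IRF7 was at 0.74 (SE 0.16, limma adjusted p = 0.108). This list's adjusted p was 0.0186 by camera, 0.0991 without mock clone 2, 0.154 without knockdown clone 2, and 0.976 with an estimated correlation. Its mean was 0.16 without knockdown clone 2, 0.48 without knockdown clone 1 and 0.17 with normexp correction.

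Xenobiotic metabolism genes averaged -0.49 ± 0.64 over 23 members, with ALDH1A1 at -0.59 (SE 0.14) and NAT2 at -0.74 (SE 0.20), neither past the test (limma adjusted p = 0.133 and 0.153). The list's adjusted p was 0.0324 by camera, 0.1497 without mock clone 1, and 0.653 with an estimated correlation. Autophagy and lysosome genes averaged 0.17 ± 0.44 over 35 members. WIPI1, an autophagosome factor, was at 1.32 (SE 0.17, limma adjusted p = 0.0524) and GABARAPL1 at 1.27 (SE 0.20, limma adjusted p = 0.0726). The list's adjusted p was 0.0375 by camera, 0.0539, 0.107 and 0.0667 without mock clone 1, mock clone 2 and knockdown clone 1, and 0.653 with an estimated correlation. DNA methylation and chromatin silencing genes averaged -0.24 ± 0.33 over 24 members, with MBD2 at 0.68 (SE 0.14) and the maintenance methylation factor gene UHRF1 at -0.80 (SE 0.19), neither past the test (limma adjusted p = 0.109 and 0.136). The list's adjusted p was 0.0375 by camera, 0.0522, 0.117 and 0.146 without mock clone 1, mock clone 2 and knockdown clone 2, and 0.653 with an estimated correlation. In limma, 0 members of the antigen presentation, xenobiotic, autophagy and methylation lists passed over all genes, and 2 higher, 0, 4 higher and 0 passed adjusted over the list alone. The xenobiotic, autophagy and methylation lists also lost the call under some settings that kept all 4 arrays. Spike-in scaling raised every difference by 0.15, and the mean of the methylation list was then -0.09 (camera adjusted p = 0.0692).

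**Figure D3:**
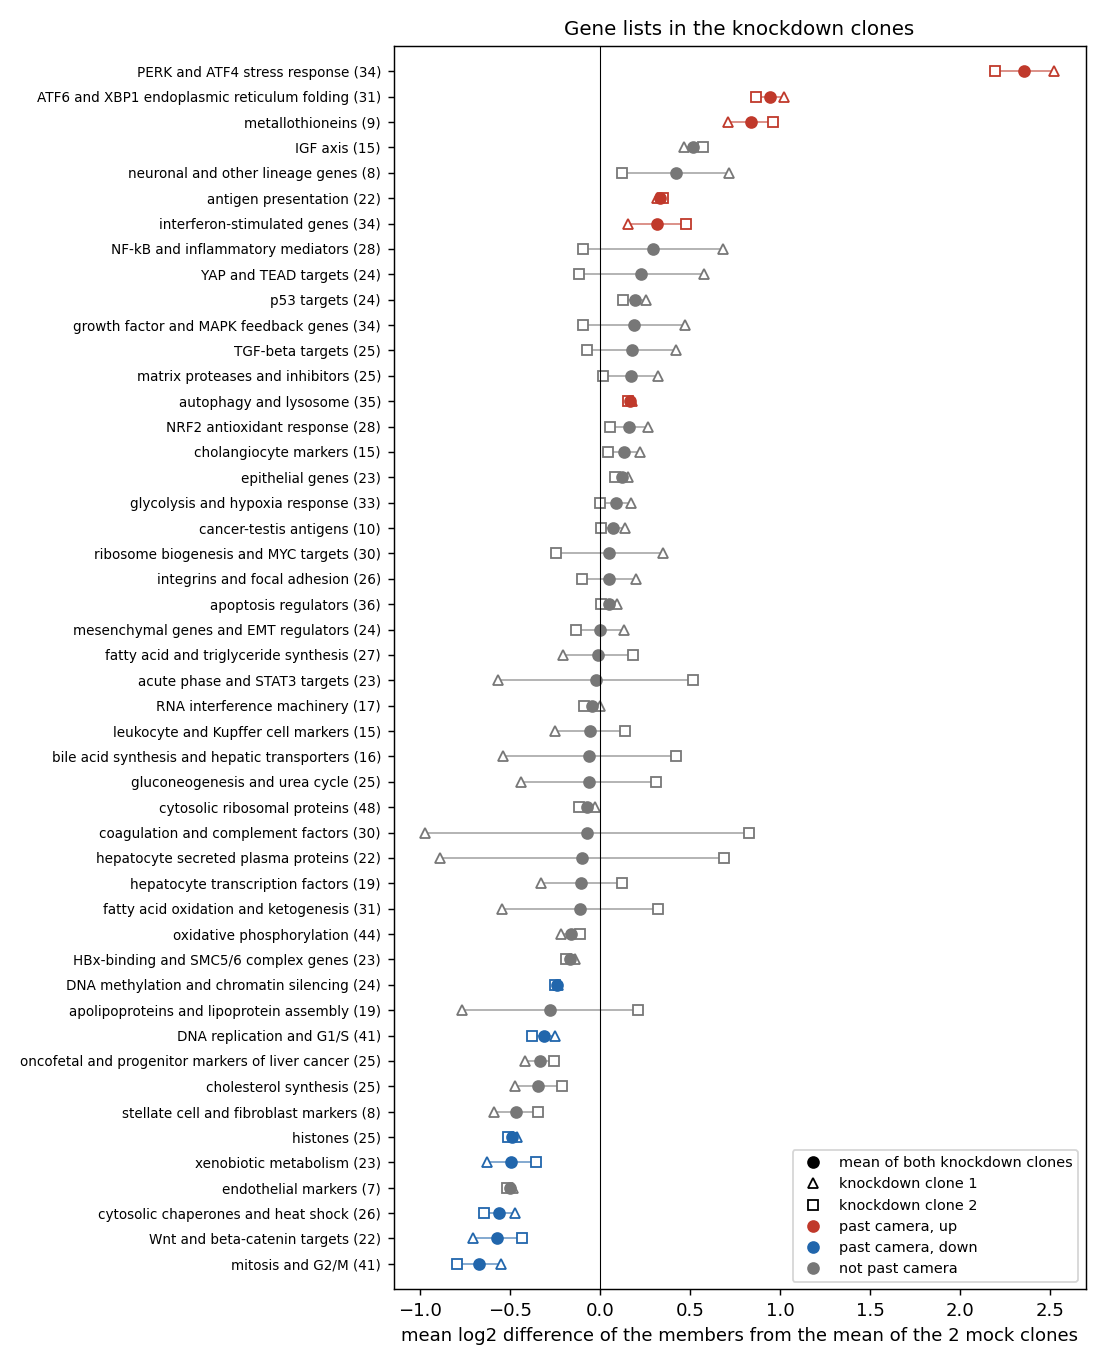
Filled circles are the mean log2 differences of the 48 gene lists from the mean of the 2 mock clones, with the number of measured members in parentheses; triangles and squares are knockdown clones 1 and 2, and red or blue lists passed camera. The PERK and ATF4 list lies farthest from 0 at 2.36, and the clones lie on opposite sides of 0 for 17 lists, none of them past camera.

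The 35 lists that did not pass camera had means between -0.50 and 0.52, and single members still passed over all genes. PCK2, the mitochondrial phosphoenolpyruvate carboxykinase, was 8.71-fold higher (log2 difference 3.12, SE 0.19, limma adjusted p = 0.0236) in the gluconeogenesis and urea cycle list, whose mean was -0.06. ACSL1, an acyl-CoA synthetase, rose by 1.80 (SE 0.21) and PLIN2, a lipid droplet coat protein, by 1.38 (SE 0.16) in the fatty acid and triglyceride synthesis list, whose mean was -0.01. IGFBP3, an IGF-binding protein, rose by 1.48 (SE 0.18, limma adjusted p = 0.0486) in the IGF axis list (mean 0.52, camera adjusted p = 0.139, but 0.0171 without mock clone 1 and 0.0462 with no filter on dim probes), and IGFBP1 was at 4.38 (SE 0.55, limma adjusted p = 0.0507). Among p53 targets (mean 0.19, camera adjusted p = 0.524), SESN2 rose by 1.86 (SE 0.16) and BBC3, the PUMA gene, by 1.77 (SE 0.18), while the antiproliferative gene BTG2 fell by 1.23 (SE 0.15). SESN2 is also a member of the PERK and ATF4 list.

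Genes of known HBx-binding proteins and of the SMC5/6 complex averaged -0.16 ± 0.34 over 23 members and did not pass with all 4 arrays (camera adjusted p = 0.132). The mean was -0.19 without knockdown clone 1, where the list passed (camera adjusted p = 0.0384), and -0.0145 with spike-in scaling, where it did not. CREBBP, a histone acetyltransferase, had the smallest p among them at -0.84 (SE 0.15, limma adjusted p = 0.0818), followed by SPHK1 at -0.55 (SE 0.12, limma adjusted p = 0.116). The RNA interference machinery averaged -0.04 ± 0.48 over 17 members (camera adjusted p = 0.778), with TLR3, a sensor of double-stranded RNA, at 1.57 (SE 0.21, limma adjusted p = 0.0575) and AGO4 at -0.61 (SE 0.22, limma adjusted p = 0.230). Oxidative phosphorylation averaged -0.16 ± 0.25 over 44 members (camera adjusted p = 0.05002, not past the threshold) and cholesterol synthesis -0.34 ± 0.42 over 25 members (camera adjusted p = 0.0770). Whether these 2 lists passed depended on the setting. Oxidative phosphorylation passed at -0.22 without mock clone 1, at -0.21 without knockdown clone 2, with median scaling and with genes with a symbol only (camera adjusted p of 0.00822, 0.0248, 0.0493 and 0.0379). It was closer to 0 and not past at -0.10 without mock clone 2, -0.07 with quantile normalization, -0.08 with the deposited table and -0.0126 with spike-in scaling (camera adjusted p of up to 0.619, with quantile normalization). The cholesterol list passed at -0.61 without mock clone 1 and at -0.47 without knockdown clone 2 (camera adjusted p of 9.91e-06 and 0.0223), and was at -0.0736 without mock clone 2 and -0.21 without knockdown clone 1, not past. It also passed with quantile normalization, the deposited table and spike-in scaling (camera adjusted p of 0.0442, 0.0450 and 0.0217).

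Markers of other liver cell types did not pass camera with all 4 arrays. Their means were -0.47 for stellate cells and fibroblasts (8 measured), -0.50 for endothelium (7 measured), -0.05 for leukocytes and Kupffer cells (15 measured) and 0.13 for cholangiocytes (15 measured). The cholangiocyte list passed without mock clone 1, at 0.67 (camera adjusted p = 0.0329). Mesenchymal genes averaged 0.00, epithelial genes 0.12 and oncofetal and progenitor markers -0.33, with camera adjusted p of 0.975, 0.653 and 0.0770. The oncofetal list passed at -0.39 without mock clone 1 and at -0.41 without knockdown clone 2 (camera adjusted p of 0.0180 and 0.0248). In the oncofetal list, SPINK1 was at -2.94 (SE 0.46, limma adjusted p = 0.0725) and TERT at -1.15 (SE 0.29, limma adjusted p = 0.145).

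For 17 of the 48 lists, of hepatocyte genes and of other genes, the knockdown clones lay on opposite sides of the mock mean. The mean of secreted plasma protein genes was 0.89 below mock in knockdown clone 1 and 0.69 above it in clone 2, and that of coagulation and complement factors 0.97 below and 0.83 above. Apolipoprotein genes were 0.76 below and 0.21 above, and fatty acid oxidation genes 0.54 below and 0.32 above. Xenobiotic metabolism genes, also hepatocyte genes, were below mock in both clones, by 0.63 and 0.35. Among other lists, ribosome biogenesis genes were 0.35 above mock in clone 1 and 0.25 below it in clone 2, and NF-kB genes 0.68 above and 0.10 below. Growth factor and MAPK feedback genes were 0.47 above and 0.09 below. In the main setting the NF-kB and growth factor lists did not pass (camera adjusted p of 0.194 and 0.122). Both passed with no filter on dim probes (camera adjusted p of 0.0154 and 0.0124), and the growth factor list also with normexp correction (camera adjusted p = 0.0372). The plasma protein, coagulation, apolipoprotein and oxidation lists did not pass camera with all 4 arrays (adjusted p of 0.894, 0.524, 0.681 and 0.913). All 4 passed downward without knockdown clone 2, and all but the apolipoprotein list passed upward without knockdown clone 1. In each, the gap between the knockdown clones was larger than the mean difference between the groups. In 12 of the 48 lists the mean, the median and the direction given by camera did not share a sign, and none of these 12 passed with all 4 arrays.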

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

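A comparison of control probes between the groups singled out 2 probes, and no test of an explanation was run on them. Of 140 control probes outside the main measurement, 38 were well above background on both knockdown arrays, and 2 of these lay higher on both knockdown arrays than on both mock arrays by more than the gap between the mock arrays. Both carry names of External RNA Controls Consortium (ERCC) spike-in transcripts. Neither was well above background on the mock arrays, so the size of the difference was not measured. The signals as recorded, relative to the 75th percentile, lay 0.62 and 0.30 log2 units apart. Background itself differed between the groups, and the negative control spots moved the other way, from -7.00 on the mock arrays to -7.66 on the knockdown arrays. Whether the spike-in transcripts were added to these samples is not given in the sources used here, and no biological explanation was tested.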

How the results depend on the processing

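Of the 13 called lists, 8 passed camera at the preset correlation in all 18 other settings. The cause of each change below was not tested unless stated. Every one of the 213 called genes kept its sign in each of these settings in which it was tested, which was largely fixed in advance. The groups did not overlap in any of the 213, so leaving out an array could not turn a sign. The smallest called difference was 1.01 log2 units, against a shift of 0.15 from spike-in scaling. Higher and lower genes numbered 66 and 4 with no filter on dim probes, 84 and 12 without the intensity trend, and 452 and 176 with the clone number as a replicate block (451 and 175 at least 2-fold). Lower genes numbered 16 with genes above background on all 4 arrays, where fewer genes were tested, and 27 with the mean of all probes. Of the settings chosen after seeing the data, spike-in scaling gave 318 higher (311 at least 2-fold), 87.4% of calls against 80.8%, and moved the median difference of all genes from -0.06 to 0.09. A floor at the weakest well-above-background signal gave 0 higher and 0 lower in limma, with 4510 at an unadjusted p under 0.05. It put 218 genes at one value on all 4 arrays, and without them 87 were higher and 7 lower. Leaving out 1 array in turn gave 25 to 405 higher (25 to 403 at least 2-fold), 2 to 316 lower (2 to 312 at least 2-fold) and 9 to 26 lists; the lone clone of a group is then assumed to vary like the other group. Lists past the test numbered 0 with an estimated correlation (1 at an unadjusted p under 0.05) and 0 with directional fry (11 unadjusted), against 13; 27 passed fry for change in either direction. The mean of the acute phase and STAT3 list turned from -0.02 to 0.0725 (camera adjusted p = 0.0462) with no filter on dim probes. Without knockdown clone 1, the means of the 5 lists named in the next sentence, none of them called in the full data, changed sign. With all 4 arrays camera already gave the upward direction for all 5, against the sign of the mean in all but ribosome biogenesis. With 1 array left out, means ranged from -0.97 to 0.83 for coagulation and complement, -0.89 to 0.69 for secreted plasma proteins, -0.56 to 0.52 for acute phase and STAT3, -0.54 to 0.32 for fatty acid oxidation, and -0.25 to 0.35 for ribosome biogenesis; the 2 ends of each range were the fits without knockdown clone 1 and without knockdown clone 2. The called xenobiotic list was lost under 6 settings, autophagy under 6 and DNA methylation under 7. Differences between clone 1 and clone 2 correlated at 0.11 across genes between the groups, and with 2 pairs this does not establish pairing. The slide as a block was not run, since there was 1 slide. Signals near background limit what can be said of dim genes: the median of the negative controls lay 0.66 log2 units lower on the knockdown arrays.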

Other observations

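The added gene lists and the genes named from them were chosen after the main results were seen, and the tests of array scaling and of slide position were chosen after the results they measure were seen; the other tests were set before their values were seen. Cytosolic aminoacyl-tRNA synthetase genes, which charge tRNAs for translation, averaged 0.91 ± 0.95 log2 units (SD over 20 genes) above mock, with 7 past the test over all genes and 11 higher and 1 lower adjusted over the list alone. GARS1 was higher by 1.96 (SE 0.14, limma adjusted p = 0.0236), NARS1 by 1.84 (SE 0.13, limma adjusted p = 0.0236) and CARS1 by 2.24 (SE 0.16, limma adjusted p = 0.0236). QARS1, VARS1 and HARS1 lay below 0, at -0.39 (SE 0.12), -0.31 (SE 0.28) and -0.09 (SE 0.18), and none of the 3 passed over all genes, while QARS1 was the 1 lower gene past the threshold adjusted over the list alone. The 17 measured mitochondrial synthetases averaged 0.05 ± 0.54, with 0 past limma over all genes. A hypothesis is that the increase may be specific to the cytosolic enzymes. The means differed by 0.86, with a permutation p across genes of 0.00185 (100000 resamples, two-sided). Of the 20 cytosolic genes, 5 were named in the PERK and ATF4 list beforehand, and without them the difference was 0.45 with a permutation p of 0.0436. Genes are not independent replicates and the permutation shuffled genes, so both p describe genes within these 4 clones and do not measure the spread between clones.

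Amino acid transporter genes averaged 0.93 ± 1.45 over 24 measured members, with 6 higher past the test over all genes, 4 of the 24 being members of the PERK and ATF4 list. Outside that list, SLC6A9, named above among the largest increases, had the largest difference of the transporters at 5.14 (SE 0.37, limma adjusted p = 0.0236). SLC7A9 was 5.01-fold higher (log2 difference 2.32, SE 0.25, limma adjusted p = 0.0398) and SLC1A5, a glutamine transporter, 2.57-fold higher (log2 difference 1.36, SE 0.14, limma adjusted p = 0.0368). SLC43A2 was at -1.82 (SE 0.23, limma adjusted p = 0.0516). The camera adjusted p over these added lists was 9.71e-07 for the transporters and 1.05e-09 for the cytosolic synthetases, and 0.278 for each with an estimated correlation. These p include the members of the PERK and ATF4 list and, for the transporters, SLC6A9, genes already seen to be higher. They are therefore not separate evidence, and no camera p without those members is given here. The cholesterol pathway without its sterol-sensing regulators averaged -0.24 ± 0.29 over 16 members (camera adjusted p = 0.120).

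The rise of the folding lists raised the hypothesis that proteasome subunit genes rise with them. Their mean was -0.234 (SD 0.20 over 31 subunits), 4 of 31 were positive and 0 passed limma over all genes or adjusted over the list alone, so these genes did not rise with the endoplasmic reticulum genes. The camera adjusted p of the subunits was 0.000755, in the downward direction, and 0.657 with an estimated correlation.

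The rise of the PERK and ATF4 list was weighed against 3 technical explanations. Array scaling or a difference in background would need the shift to shrink under another setting, and over 7 settings of scaling, background and filter the mean of the list was never below 2.16. The filter settings change no signal. Spike-in and median scaling move all genes by the same amount, small beside this mean, so these settings could hardly have removed the shift. A single deviating clone would need 1 of the 4 pairs of a knockdown and a mock array to lie near 0, and the smallest pair difference was 2.13. Position on the slide cannot be told apart from the group, since 0 slide rows held arrays of both groups. The knockdown itself, an off-target effect of the RNA interference construct and a stress of the clones during selection also stay open, since each group has its own clones and no other construct was measured.

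The lower mitosis and G2/M list was weighed in the same way. Over the same 7 settings its mean stayed at or below -0.52, and over the 4 pairs of arrays at or below -0.47, which argues against scaling and against a single clone as the whole of it. The filter settings change no signal here either, so the point on scaling rests on the scaling and background settings. Slide position and group cannot be told apart here either. A hypothesis is that the knockdown clones held fewer dividing cells, which may follow from the knockdown or from culture density, and neither was measured.

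The genes that switched between almost silent and high, such as SLFN11 and S100A6, may be differences that any pair of clones of this line shows rather than differences of the knockdown. The 2 mock clones differed by at least 16-fold at 9 genes and the 2 knockdown clones at 7, and a knockdown and a mock clone at 36 to 79, counted on the processed signal with dim values as recorded. The larger within-group count, 9, lies between what that explanation needs and what would exclude it, so clonal differences stay open for these genes. At 17 genes both knockdown clones lay at least 16-fold apart from both mock clones on the same side. The other 2 ways to split the 4 arrays into pairs gave 0 such genes each, which the filter on dim probes largely fixed in advance. Only genes well above background on both mock arrays or on both knockdown arrays were counted. A gene high in a single clone of each group and silent in the others was therefore left out. The same filter can lower the within-group counts of 9 and 7, so neither comparison can decide the question.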
